A study of Mus musculus with 2 samples.

How the data were processed

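DNase-seq libraries of gastrocnemius muscle from male B6CASTF1/J mice aged 2 months were used, 1 group of 2 libraries. Per the labels they are biological replicates 1 and 2 from animals numbered 5 and 6. The labels give both the same donor identifier, so that the libraries come from separate animals rests on the animal numbers alone. No test between the libraries was made, since each is a single sample.

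For each library the authors deposited peaks, footprints and a per-base false discovery rate of the cut rate, on mm10, per the text deposited with each library. That text lists peaks and rates as derived from the library's own filtered alignments, so replicates were not pooled. The peak files deposited by the authors carry a signal value per peak, and all other scores in them are constant. Signal values were whole multiples of 1 step per library (0.00433 in replicate 1 and 0.00419 in replicate 2, for 100% of distinct values). The scale of that step is not stated, so the signal is used to rank and filter peaks within a library, and levels are set side by side only as the authors' values. The q-value files deposited by the authors list bases with a false discovery rate under 0.05, which came to 55.8 and 61.3 Mb. The aligner, the peak and footprint callers and their settings are not given in the sources used here.

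Each library has 2 peak files. On the rates, the lowest value inside every peak of the smaller file was under 0.001, and in the larger file it ranged up to 0.05. The smaller files, with 119631 and 124152 peaks, were used for the main results, and the larger ones, with 191996 and 206192 peaks, as an alternative. The median peak width was 180 bp in both smaller files, and the median signal was 1.12 and 1.04. Footprints had median widths of 11 and 10 bp and carry the value 0.01 throughout, so they could not be ranked. Of them, 69.0% and 68.4% lay in peaks of the smaller files. Read totals are not among the files used, so depth is unknown beyond these numbers.

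Gene positions were taken from GENCODE vM21 on GRCm38.p6, the assembly of mm10, with 21829 protein-coding genes and 54333 transcript starts. Coordinates are 1-based. A gene was open when peaks of both libraries met the 500 bp on either side of any of its starts. The promoter signal of a gene is the highest of each library in those windows, so the signals of the libraries can come from different peaks. Shared regions are merged overlapping peaks of both libraries, and distal ones lie farther than 1 kb from every start. Random placement was done 10 times per library. Intervals of shares of genes are exact Clopper-Pearson 95% intervals and cover counting error only.

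Gene lists and motif consensus sequences were fixed before the data were examined, as were the tests, the windows and the rule for named genes. There were 26 lists and 34 motifs, of which HNF1 and p53 occurred in neither regions nor flanks and are not reported. A list's share of open promoters was compared with 10000 random lists of the same size, matched on quintile of promoter CpG content and on the number of starts. Its mean number of distal regions was compared with 10000 lists matched on decile of searched length. Random lists were drawn with replacement from the other genes of the same stratum, and the p-values from them are called permutation p. Both are two-sided, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05, and the smallest p the random lists can give is 0.0002. Genes are not replicates, so these p-values describe the libraries at hand. Motifs in the central 150 bp of distal regions were counted on both strands. Motifs in footprints, extended by 5 bp, were compared with windows of the same widths in peaks outside footprints. Motif odds ratios are computed with a small constant added to each count, and their p-values come from Fisher's exact test. Fast and slow fibre genes were compared by Fisher's exact test on open promoters and by 100000 permutations of list membership on distal regions. Neighbouring windows are not independent, so the intervals are too narrow by an unknown amount.

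Named are, for each list, up to 4 open members with the strongest promoter signal and up to 3 without a promoter peak in either library. To these come the 10 genes with most distal regions per kb, the 10 strongest shared regions, the 5 strongest peaks of each library alone and 16 loci. Not every gene so named is printed. A withheld item is not reported here. Chrne, the genes at runs and the neighbours of dense genes were named after their values were seen.

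Other promoter windows, flanks, overlaps, peak subsets, random lists, GC-matched flanks and each library alone were planned as alternatives. Runs of weak peaks, lists and motifs in the larger peak set, 1 gene per neighbourhood, the matched footprint background, footprints inside peaks and the fast against slow comparisons were added after the data were seen. The tests were checked on simulated data. The promoter test called 98% of changed and 1% of unchanged lists of 16 genes. Changed lists were simulated with nearly all promoters open and unchanged ones with a lower share. The 98% therefore does not hold for smaller changes, or for lists whose matched lists were already mostly open. The distal test called 4% of lists raised 2.5-fold and 30% of lists raised 4-fold, and none of 100 unchanged lists. In simulation p-values were adjusted over 100 changed and 100 unchanged lists together, against 26 lists in the data. The shares called are therefore not the power of the tests as run. Motifs planted in 10, 5 and 2% of 20000 windows raised the share found by 9.89, 4.97 and 2.00 percentage points, and 1 of 31 motifs not planted was called. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.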

Results

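Accessible chromatin was mapped by DNase-seq, in which DNase I cuts mark DNA that is not wrapped tightly in nucleosomes or covered by proteins, in the gastrocnemius, a calf muscle of the hind leg. The tissue came from male B6CASTF1/J mice, the F1 hybrid of C57BL/6J and CAST/EiJ, aged 2 months. The series holds 1 group with 2 libraries, whose labels carry the animal numbers 5 and 6, and it implies no contrast between conditions. The questions are which sites were open in both libraries, which genes and sequence motifs lay at them, and how far the libraries differed. The number of reads behind each library is unknown here, so no interval from read counts is given. At a false discovery rate under 0.001, 119631 peaks covering 22.0 Mb were listed for replicate 1 and 124152 peaks covering 23.0 Mb for replicate 2. Footprints, short stretches within open DNA that were protected from cutting, numbered 463993 and 407052.

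Most open sites were found in both libraries. Of the replicate 1 peaks 73.9% overlapped a peak of replicate 2 by at least 1 bp, and 71.1% of the replicate 2 peaks overlapped replicate 1 (mean 72.5%). These are the 2 directions of 1 comparison, so no spread is given. Random placement of the same peaks on the same chromosomes gave 1.93% and 1.86%. The overlapping peaks formed 87142 shared regions, and the Jaccard index over bases was 0.498. Across these regions, which are not independent replicates, the peak signal of the authors had a Spearman rho of 0.909 between the libraries. Among the strongest 10000 peaks of each library the overlap was 87.3%, and over the larger peak sets listed at a false discovery rate under 0.05 it averaged 66.98%. Of the peaks in the smaller files, 86.8% of replicate 1 and 79.1% of replicate 2 overlapped a larger-set peak of the other library.

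Replicate 2 held many weak peaks that overlapped none in the smaller peak file of replicate 1. Of its 23215 peaks of signal under 0.4, 15773 lay in runs, defined as at least 5 peaks of signal under 0.4 within 5 kb of a midpoint on either side, a definition chosen after the data were seen. Replicate 2 had 1180 such runs over 10.97 Mb against 270 over 1.92 Mb in replicate 1, and they took 12.7% and 2.32% of the peaks. The longest in replicate 2 covered 60.4 kb at Tbc1d14 and D5Ertd579e on chromosome 5, and others covered 52.7 kb at Pdgfrb and Csf1r and 49.4 kb within Ttn, the titin gene. Only 3.84% of the replicate 2 peaks in runs overlapped a replicate 1 peak of the smaller file. With runs left out of both libraries, the mean overlap was 77.9%.

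Footprints were shared less often than peaks. Of the replicate 1 footprints 49.5% overlapped one of replicate 2, against 57.6% in the other direction (mean 53.5%). Inside the shared regions the shares were 64.2% and 72.8%, against 37.0% and 40.5% for footprints placed at random within the same regions. A shared region held on average 3.07 footprints of replicate 1 and 2.77 of replicate 2.

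Open sites gathered at the starts of protein-coding genes. Within 500 bp of a transcript start lay 19.4% ± 0.390 of the peaks (SD, n = 2), against 1.65% and 1.69% under random placement. Introns held 40.4% ± 1.38, intergenic DNA 34.3% ± 2.34 and exons 5.89% ± 1.34 (SD, n = 2). Promoter peaks were stronger, with a median signal of 3.08 in replicate 1 and 3.95 in replicate 2, against 0.979 and 0.880 for all other peaks. Chromosome 11 was the densest, with 76.0 and 86.6 peaks per Mb. The X chromosome held 16.3 and 14.2 peaks per Mb, or 0.344 and 0.287 of the autosomal density, and the Y chromosome 38 and 68 peaks in all. In the larger sets the X ratios were 0.3953 and 0.3935. The mice were male, and whether X copy number lowered these values was not tested. Of 21829 protein-coding genes, 13679 (62.7%) had a promoter peak in both libraries, with 64.0% on autosomes and 45.3% on X. The strongest 50% of peaks lay at promoters in 30.1% of cases.

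The strongest shared regions were mostly promoters. By mean rank of the authors' signal they were led by a region at chromosome 13, 17694881 to 17695100 (mm10), 0.201 kb from the start of Mplkip and within an intron of Sugct, with signals of 60.1 and 67.8. Next came chromosome 17, 6430021 to 6430180, 0.011 kb from the start of Dynlt1b, with 56.3 and 95.9. Regions at Bahcc1, Hjurp, Dnpep, Ctdsp2, Fzr1, Snrnp70 and Serf2 also lay within 0.2 kb of a start. The exception among the 10 was chromosome 5, 25529581 to 25529860, intergenic and 13.7 kb from Cct8l1. Of the 5 strongest peaks found in each library alone, all lay at promoters except 1 of replicate 1 at chromosome 7, 27490861 to 27491020, which was intergenic and 3.57 kb from Sertad1. The replicate 1 peak at chromosome 14, 55015301 to 55015480, and the replicate 2 peak at 55015061 to 55015260 are neighbours at the start of Ngdn that do not overlap. Replicate 2 alone had a peak of signal 20.7 at a start of Atf3, a stress-induced transcription factor, whose promoter peaks in both libraries had signals of 23.9 and 32.65. Every one of these single-library peaks held footprints of both libraries, with 4 of replicate 1 in the Atf3 peak. They are therefore not shown to be sites open in a single library.

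Promoters of shared sarcomere, fast fibre, myogenic factor and neuromuscular junction genes were open more often than in matched lists. Slow fibre genes, described below, were not called. All 25 genes of the shared sarcomere and triad list had a promoter peak in both libraries, against a median of 44.0% in random lists matched on promoter CpG content and number of starts (adjusted permutation p = 0.0013). Among them Myom1, which encodes the M-band protein myomesin, had signals of 20.3 and 36.1, the creatine kinase gene Ckm 13.9 and 22.9, the desmin gene Des 10.8 and 16.03, and the skeletal actin gene Acta1 10.8 and 14.9. Of the fast fibre genes 14 of 16 were open (87.5%, exact 95% interval 61.7 to 98.5%, against 37.5%, adjusted permutation p = 0.0013). Among the strongest were Mylpf, the fast regulatory light chain, with 11.3 and 14.0, Actn3 with 8.83 and 15.5, Mylk2 with 7.29 and 12.9, and the calcium pump gene Atp2a1 with 7.02 and 10.6. Myh4, the fastest myosin heavy chain gene, was open at 1.35 and 1.36, whereas Myh2 had no promoter peak. All 20 myogenic and fibre-type transcription factors were open (adjusted permutation p = 0.0125), including Mafa, Mef2a and Mef2d. At the neuromuscular junction list 11 of 13 genes were open (adjusted permutation p = 0.0125). There the acetylcholine receptor subunit genes differed: Chrnb1 had signals of 18.4 and 18.4 and Chrne, the adult subunit, 3.65 and 4.36, while Chrng, the fetal subunit, had no promoter peak.

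Energy metabolism genes were open throughout. All 15 oxidative metabolism genes and all 16 genes of glucose and glycogen metabolism had promoter peaks in both libraries (both adjusted permutation p = 0.00446). Esrra, a nuclear receptor that drives mitochondrial genes, had signals of 33.0 and 45.5, Ppard 18.0 and 30.6, and Pdk4, which restrains pyruvate oxidation, 17.5 and 14.4. Gys1, muscle glycogen synthase, had 33.0 and 40.9, Pkm 18.1 and 21.7, and Ldha 12.8 and 23.3. All 13 atrophy and growth genes, 16 core clock genes, 16 immediate early and heat shock genes and 15 housekeeping genes were open too. Matched random lists were open at medians of 87.5 to 93.8%, and these 4 lists were not called. At 100% they had the highest share possible, so the test against matched lists could not have called them higher. Pgk1 belongs to both the glucose and the housekeeping list.

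Fast fibre genes were more often open than slow fibre genes when both libraries were required. Of the slow fibre list 7 of 14 promoters were open in both libraries, close to the 42.9% of matched random lists (adjusted permutation p = 0.910), and Myh7, the slow myosin heavy chain gene, Tnnc1 and Tnnt1 had no promoter peak. Slow fibre promoters with the highest signals were those of Tpm3 with 16.6 and 11.02, Atp2a2 with 6.69 and 12.9 and Ankrd2 with 5.78 and 7.05. The share of open promoters differed between the lists (Fisher's exact test, two-sided, p = 0.0457). Fast fibre genes had 9.50 distal regions each against 5.07 (two-sided permutation test, p = 0.0470), and 17.2 against 8.12 per 100 kb searched (permutation p = 0.0353). With 1 gene kept per neighbourhood the distal means were 10.4 and 5.07 (permutation p = 0.0242). These 4 comparisons were added after the data were seen and have an adjusted p of 0.0470 each. The promoter difference was not called without replicate 1 (15 of 16 fast against 10 of 14 slow genes, Fisher's exact p = 0.157), without replicate 2 (14 against 8, p = 0.101) or in the larger sets (15 against 9, p = 0.0725). It was called among the strongest 50% of peaks (14 against 5, Fisher's exact p = 0.00683) and without runs (14 against 7, p = 0.0457). The distal difference was not called among the strongest 50% of peaks (5.06 against 3.14 regions per gene, permutation p = 0.101), but was with the peaks of replicate 2 alone (20.7 against 10.6, permutation p = 0.0371) and of replicate 1 alone (14.5 against 7.43, permutation p = 0.0362). In the larger sets the distal difference was called too (14.9 against 7.07, permutation p = 0.00576).

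Marker genes of some other cell types of muscle were open more often than in matched lists. Of the fibro-adipogenic and fibroblast list 13 of 16 genes were open, against 37.5% in matched random lists (adjusted permutation p = 0.0013). Col1a1 had signals of 6.77 and 7.70 and Cd34 5.77 and 5.56. Of the mural and smooth muscle list 11 of 12 were open (adjusted permutation p = 0.0111), among them Pdgfrb with 5.28 and 4.77, Cspg4 with 4.52 and 4.78 and Abcc9 with 2.70 and 5.40. Satellite cell genes were open in 11 of 13 cases and endothelial genes in 12 of 15, neither above matched lists (adjusted permutation p = 0.804 and 0.250). Spry1, which keeps satellite cells quiescent, had signals of 5.79 and 11.2, and Calcr had no promoter peak. The other lists without a call were tenocyte with 7 of 10, Schwann cell with 6 of 12, adipocyte with 5 of 11, macrophage and myeloid with 5 of 14, lymphocyte with 2 of 12 and erythroid with 2 of 11. In the larger peak sets all 15 endothelial genes (adjusted permutation p = 0.0078) and 9 macrophage genes (adjusted permutation p = 0.0390) were open, above matched lists.

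Promoter peaks were fewer than in matched lists at cardiac, hepatocyte, neuronal and vomeronasal receptor genes. Cardiac genes were open in 2 of 13 cases, Gata4 and Hcn4, against 53.8% in matched lists (adjusted permutation p = 0.00446), and Myh6 and Hand1 had no promoter peak. The cardiac call rests on the smaller peak sets and on requiring both libraries: either library alone gave 30.8% (adjusted permutation p = 0.0754 without replicate 1 and 0.09999 without replicate 2), and the larger sets gave 53.8% (adjusted permutation p = 0.905). Of 16 hepatocyte genes only Apoh was open (adjusted permutation p = 0.0326), and Alb, the albumin gene, had no promoter peak in either library. Neuronal genes were open in 7 of 14 cases against 78.6% (adjusted permutation p = 0.0481), a call lost under 6 of the 9 other settings, including a window of 1 kb (64.3%, adjusted permutation p = 0.465). Of 330 vomeronasal receptor genes 1 was open, Vmn1r4, against 7.58% (adjusted permutation p = 0.0013). These receptors form a large family of near copies, so their values are uncertain. Hindlimb position genes were open in 11 of 13 cases (adjusted permutation p = 0.927), led by Hoxc10 with 15.03 and 19.3.

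The calls above compare each list with genes of like promoters. Against unmatched random lists the fast fibre, neuromuscular junction, fibro-adipogenic and mural lists were not called (adjusted permutation p = 0.108, 0.239, 0.257 and 0.103); of all genes 62.7% were open. Against them the atrophy, clock, immediate early and housekeeping lists were called higher (adjusted permutation p = 0.0173, 0.00260, 0.00260 and 0.00756), and the lymphocyte and erythroid lists lower (0.00728 and 0.0180). Among the strongest 50% of peaks the mural list lost its call at 50% of genes (adjusted permutation p = 0.896), as did the neuromuscular junction (0.128) and hepatocyte lists (0.178). The myogenic factor list lost its call with a 250 bp window (adjusted permutation p = 0.329). When 50% of both peaks had to overlap, the myogenic factor (adjusted permutation p = 0.0652), neuromuscular junction (0.0608) and hepatocyte lists (0.0608) lost theirs.

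**Figure D1:**
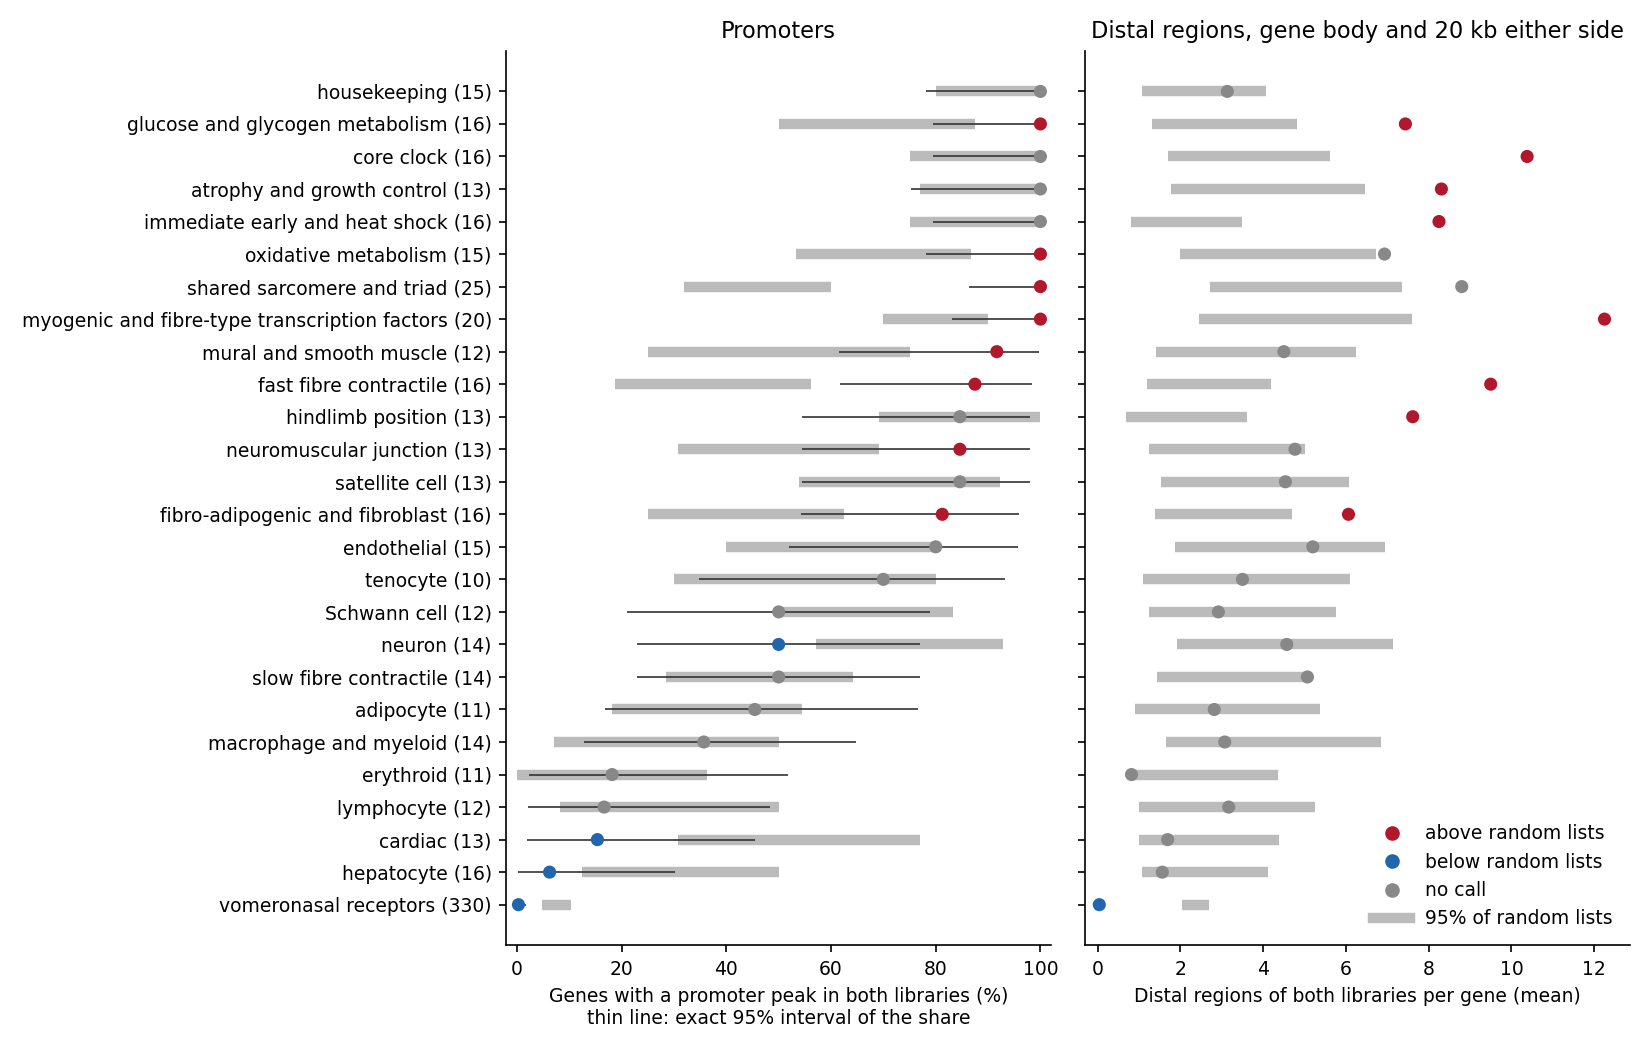
Left, share of each gene list with a promoter peak in both libraries (%), with the exact 95% interval as a thin line; right, mean number of distal regions of both libraries per gene. Grey bars span the middle 95% of matched random lists, and numbers in brackets count genes. Shared sarcomere genes sit at 100%, while cardiac genes sit at 15.4% on the left and at 1.69 regions per gene, within the grey bar, on the right.

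Distal regions, more than 1 kb from any start and within the gene body or 20 kb either side, crowded around fast fibre, clock and immediate early genes. Fast fibre genes had a mean of 9.50 distal regions of both libraries against 2.38 in random lists matched on searched length (adjusted permutation p = 0.0013). Atp2a1 had 23, Mylk2 18 and Mylpf 4. Immediate early and heat shock genes had 8.25 against 1.88 (adjusted permutation p = 0.0013), with 17 at Dusp1 and 8 at Atf3. Core clock genes had 10.4 against 3.19 (adjusted permutation p = 0.0104), with 30 at Nr1d1, which encodes REV-ERB alpha, 17 at Tef and 9 at Dbp. Myogenic and fibre-type factors had 12.2 against 4.45 (adjusted permutation p = 0.0295), with 20 at Mef2d. Glucose and glycogen genes had 7.44 against 2.62 (adjusted permutation p = 0.0121), atrophy and growth genes 8.31 against 3.62 (adjusted permutation p = 0.0273) and fibro-adipogenic genes 6.06 against 2.75 (adjusted permutation p = 0.0141). The last pair lost their calls without replicate 1 (adjusted permutation p = 0.165 and 0.375), and the fibro-adipogenic list also against unmatched lists (0.0997).

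Shared sarcomere genes had 8.80 distal regions against 4.60, just outside the threshold (adjusted permutation p = 0.0510). They were called higher with flanks of 50 kb (adjusted permutation p = 0.0380), among the strongest 50% of peaks (0.0302), in the larger sets (0.0400), against unmatched lists (0.0239) and in replicate 2 alone (0.0342). No call was made in replicate 1 alone (adjusted permutation p = 0.0510), without runs (0.0541), with 1 gene per neighbourhood (0.0520) or with flanks of 5 kb (0.0764). Counting all distal peaks of a single library, shared or not, they had 21.0 each in replicate 2, against 12.3 in replicate 1. For fast fibre genes the same values were 20.7 and 14.5, for glucose genes 15.9 and 10.6, for clock genes 17.5 and 13.2 and for hindlimb genes 22.1 and 11.1. Fibro-adipogenic genes had 7.56 and 9.88 and vomeronasal receptor genes 0.142 and 0.0879. Hindlimb position genes had 7.62 against 1.85 (adjusted permutation p = 0.0013), but Hox genes lie in clusters and share regions. With 1 gene per neighbourhood 6 of the 13 genes were left, with 5.83 against 2.00, and the call was lost (adjusted permutation p = 0.0582). Vomeronasal receptor genes had 0.0394 against 2.34 (adjusted permutation p = 0.0013). The remaining 16 lists besides sarcomere genes, among them slow fibre (5.07, adjusted permutation p = 0.107), oxidative metabolism (6.93, adjusted permutation p = 0.0988), neuromuscular junction (4.77, adjusted permutation p = 0.143) and erythroid genes (0.818, adjusted permutation p = 0.107), were not called. A list without a call is not shown to be ordinary: of simulated lists of 16 genes with distal counts raised 2.5-fold, the test called 4%, and 30% of those raised 4-fold. The simulation adjusted over more lists than the data, so these shares are not the power of the test as run.

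Single loci showed how the regions lay. At Acta1 (chromosome 8, 123891769 to 123894751) 11 shared regions were found, and the promoter region at 123894801 to 123895040 held myogenic E-box, TEAD and SRF CArG motifs. A region 22.5 kb away, at 123872161 to 123872360 in an intron of Gm20388, held MEF2 and E-box motifs with signals of 5.38 and 8.05; its nearest start is that of Ccsap, at 12.1 kb. Des (chromosome 1, 75360329 to 75368579) had 19 shared regions, of which 13 were distal. The strongest distal one, with signals of 8.27 and 12.5 at 75371441 to 75371660, lay 11.2 kb from the start of Des but 3.75 kb from that of Speg. Mb, the myoglobin gene on chromosome 15, had 22 shared regions, with a distal maximum of 8.89 and 10.03 at 77036761 to 77036960 in its own intron, 8.21 kb from the start of Apol6. At Ckm on chromosome 7 a region at 19411881 to 19412100, 0.928 kb from a start, held a MEF2 motif. Ckm had 4 distal regions in both libraries. All distal peaks of replicate 2 there, shared or not, numbered 29, and 24 with runs left out.

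The myogenic regulators were open to different degrees. Myod1 had a promoter signal of 9.07 and 13.1 and 5 distal regions, Myog 2.47 and 3.38 with 9, and Myf6 1.15 and 1.36 with 3. The Myf6 signals came from a different region in each library, as did the Myh4 promoter signals given above. Pax7, the satellite cell factor, was open at 0.810 and 1.38 with 7 distal regions. Myh4 on chromosome 11 had 8 shared regions, 4 of them distal, against a single one, 7.73 kb away, at Myh7 on chromosome 14. Pitx1, which specifies the hindlimb, had a promoter peak of 0.977 in replicate 2 only but 5 distal regions, of which the strongest, with 4.21 and 5.03 at chromosome 13, 55850721 to 55851040, held MEF2 and E-box motifs. Tbx5, its forelimb counterpart, had a promoter peak of 0.515 in replicate 1 only and 2 distal regions. Counting all distal peaks of a single library, shared or not, both genes had 5 in replicate 1, against 13 at Pitx1 and 2 at Tbx5 in replicate 2. Fbxo32, an atrophy ligase gene, was open at 8.39 and 10.8 with 8 distal regions, Ppargc1a at 1.65 and 1.84 with 5, and the clock gene Per2 at 15.04 and 23.0 with 11. Alb had none.

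**Figure D2:**
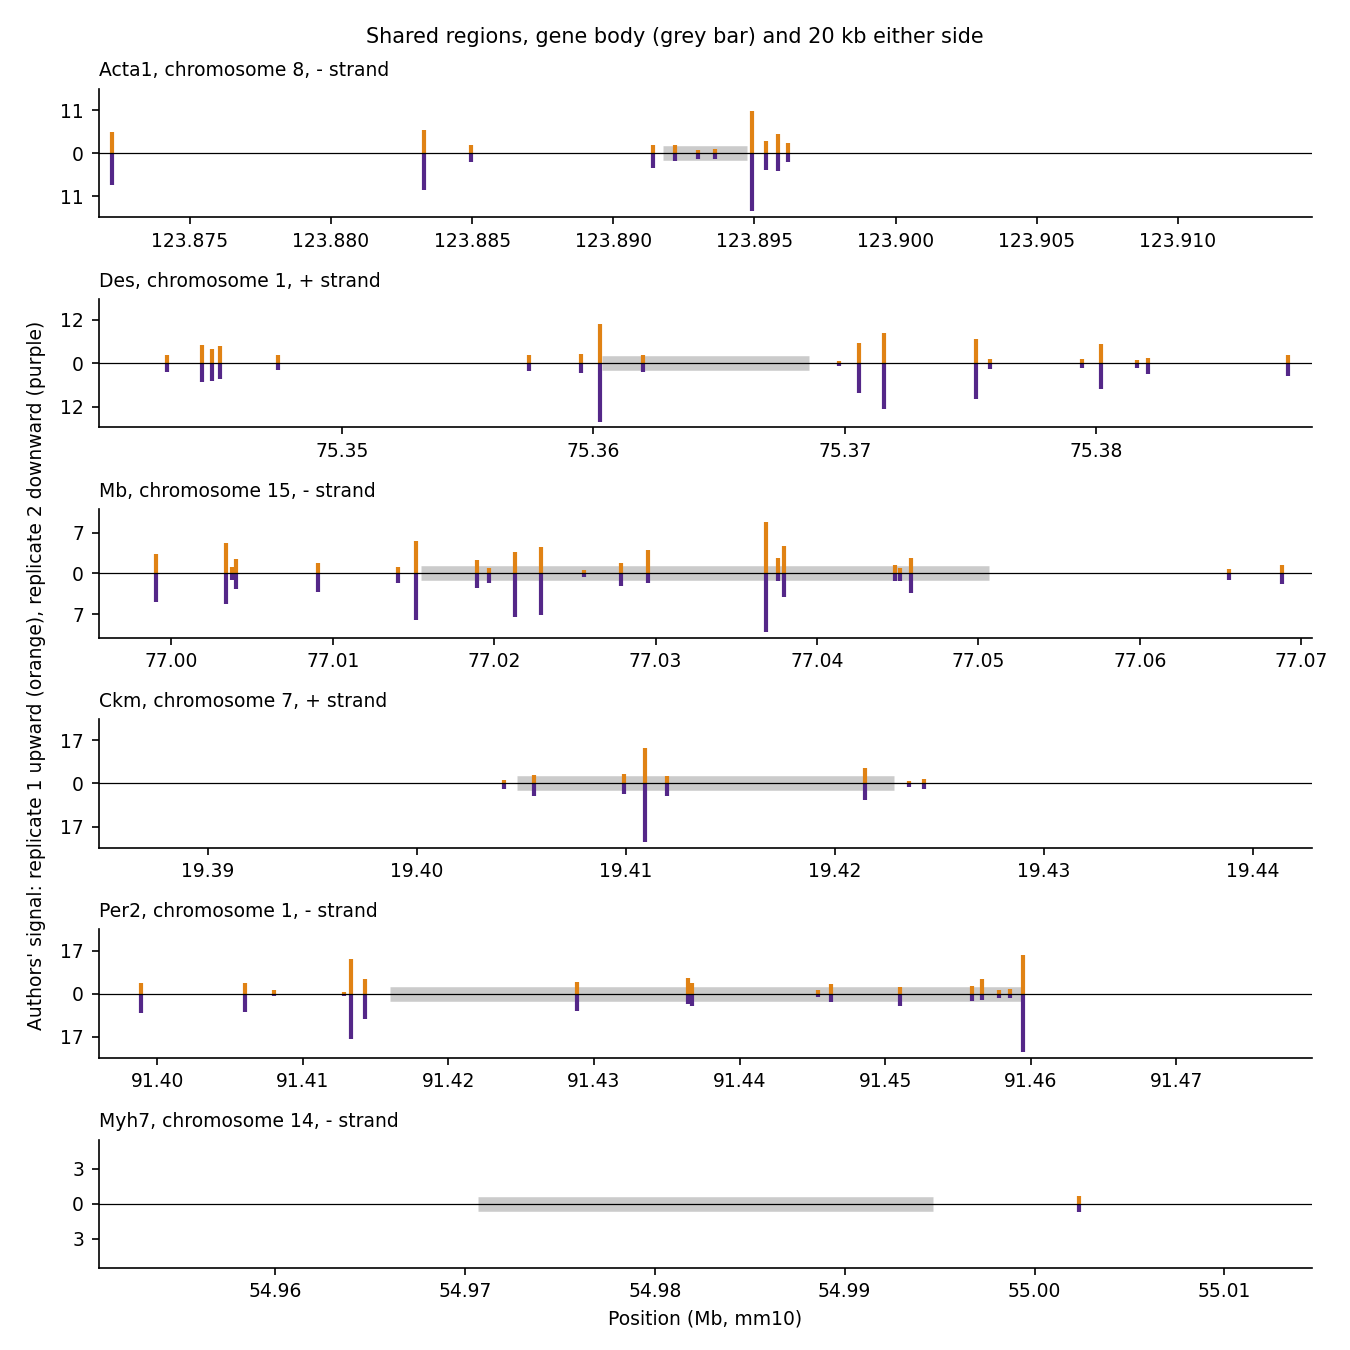
Shared regions at Acta1, Des, Mb, Ckm, Per2 and Myh7 by position (Mb, mm10), over the gene body (grey bar) and 20 kb either side. Bar height is the peak signal of the authors, upward for replicate 1 and downward for replicate 2. Mb shows 22 shared regions and Myh7 1.

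The genes with the most distal regions per kb lay in a few neighbourhoods. Nr1d1 and its neighbour Thra, the thyroid hormone receptor alpha gene, had 30 and 43 on chromosome 11. Per1, Vamp2, Hes7 and 9130213A22Rik, which also adjoin each other on chromosome 11, had 28, 24, 24 and 24, and share regions. G430095P16Rik had 27 on chromosome 8 and Fscn2 23 on chromosome 11. Lgals3bp had 35 and Sik1 27, but with runs left out these fell to 3 and 8, while 8 of the 10 genes kept their place. In replicate 2 alone only G430095P16Rik remained among the 10 densest, and in replicate 1 alone 5 of them did.

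Distal regions were rich in motifs of architectural, muscle and other factors. The central 150 bp of 63000 distal regions were compared with flanks 1 kb away that met no peak. The motif of CTCF, which anchors chromatin loops, was in 6.73% of regions and 0.0474% of flanks (odds ratio 151, 95% interval 115 to 199, and 228 in the central 100 bp). The myogenic E-box CAGCTG, bound by MyoD and its relatives, was in 21.9% against 6.94% (3.76, 3.64 to 3.87). MEF2, their partner, had an odds ratio of 3.59 (3.11 to 4.16), a paired E-box 4.47 (2.78 to 7.20), the MEF3 site 2.44 (2.02 to 2.95) and TEAD 1.48 (1.40 to 1.57). The NFI palindrome reached 14.6 (6.48 to 32.9), and the shorter NFI site lay in 40.7% of regions against 16.5% of flanks. REST, a repressor of neuronal genes, reached 34.0 (13.2 to 87.7), on 89 regions. The palindrome of the glucocorticoid and androgen receptors had 4.74 (3.83 to 5.87), AP-1 3.002 (2.86 to 3.15), CREB/ATF 4.47 (3.55 to 5.62) and ROR/REV-ERB 2.00 (1.68 to 2.37). By Fisher's exact test with Benjamini-Hochberg adjustment over 34 motifs, 20 were more frequent and 6 less frequent in regions.

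Several of these depended on base composition. Regions had a mean GC content of 54.3% and flanks 45.4%. Against flanks matched on GC content the odds ratio of MEF2 rose to 13.1 (9.33 to 18.5), and that of ROR/REV-ERB to 3.02, while those of the E-box, paired E-box, SP/KLF, NRF1 and REST fell to 2.36, 1.975, 1.19, 2.59 and 20.6. GATA remained depleted, at 0.345 and then 0.640 (0.508 to 0.805). FOX turned from 0.567 to 1.29 and the D-box of the clock factors DBP, TEF and HLF from 0.715 to 2.61. POU turned from 0.463 to 1.07, with no call after matching, and SOX and ERR motifs lost their depletion (0.855 and 0.899). PU.1 lost its enrichment (1.21). With matching 23 motifs were more frequent and 1 less frequent. Without replicate 1 YY1 was also enriched (2.70) and RUNX depleted (0.895), and among the strongest 50% of peaks the D-box was not called (0.859).

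Footprints held another selection of motifs. All footprints, of which 69.0% and 68.4% lay in peaks, were compared with windows of the same widths in peaks outside footprints. These windows were not matched to the footprints on promoter or distal place. Among motifs with a finite odds ratio in both libraries, footprints of replicate 1 and replicate 2 were most enriched in the NFI palindrome (odds ratios 106 and 77.7), CTCF (73.0 and 71.8), NRF1 (35.3 and 82.4) and REST (24.3 and 39.9). Promoter motifs followed, with CREB/ATF at 11.6 and 9.49, SP/KLF at 10.3 and 8.34, YY1 at 7.67 and 5.36 and ETS at 3.71 and 4.14. The NFI palindrome was in 1 background window per library, so its ratio has an interval of 21.2 to 528 in replicate 1. The myogenic E-box was only slightly enriched, at 1.17 (1.14 to 1.20) and 1.32 (1.29 to 1.36). The proneural E-box CAGATGG was enriched more, at 1.41 against 1.24 for the myogenic one (geometric means over libraries). MEF2 was not called (0.904 and 0.839), but with a background matched on GC content and width, a setting chosen after the data were seen, it was enriched at 1.60 and 1.51. TEAD moved from 0.868 and 0.912 to 1.07 and 1.20, and RUNX from 0.847 and 0.736 to 1.09 and 1.21, and both lost their depletion without being called enriched in both libraries. The receptor palindrome, frequent in distal regions, was depleted in footprints (0.285 and 0.612), as were FOX (0.327 and 0.362) and GATA (0.359 and 0.373). With the matched background the palindrome lost its call (0.331 and 0.794), as did ERR, ROR/REV-ERB and SOX motifs, while FOX and GATA kept theirs. Without the extension of footprints by 5 bp the ratios of several motifs lay farther from 1 (geometric means). Among these were CTCF at 191, NRF1 at 93.2, REST at 57.8, CREB/ATF at 21.7 and SP/KLF at 19.1. On the depleted side they were FOX at 0.155, GATA at 0.140 and the palindrome at 0.246. Not every motif moved this way, as MEF2, called in neither setting, went from 0.871 to 1.07. With the matched background SP/KLF fell to 5.12 and NRF1 to 34.6. The myogenic E-box fell to 1.16 there, while the proneural E-box rose to 1.54. With footprints inside peaks alone TEAD and ROR/REV-ERB were not called. In both libraries 13 motifs were more and 10 less frequent in footprints, and 17 and 4 with the matched background.

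**Figure D3:**
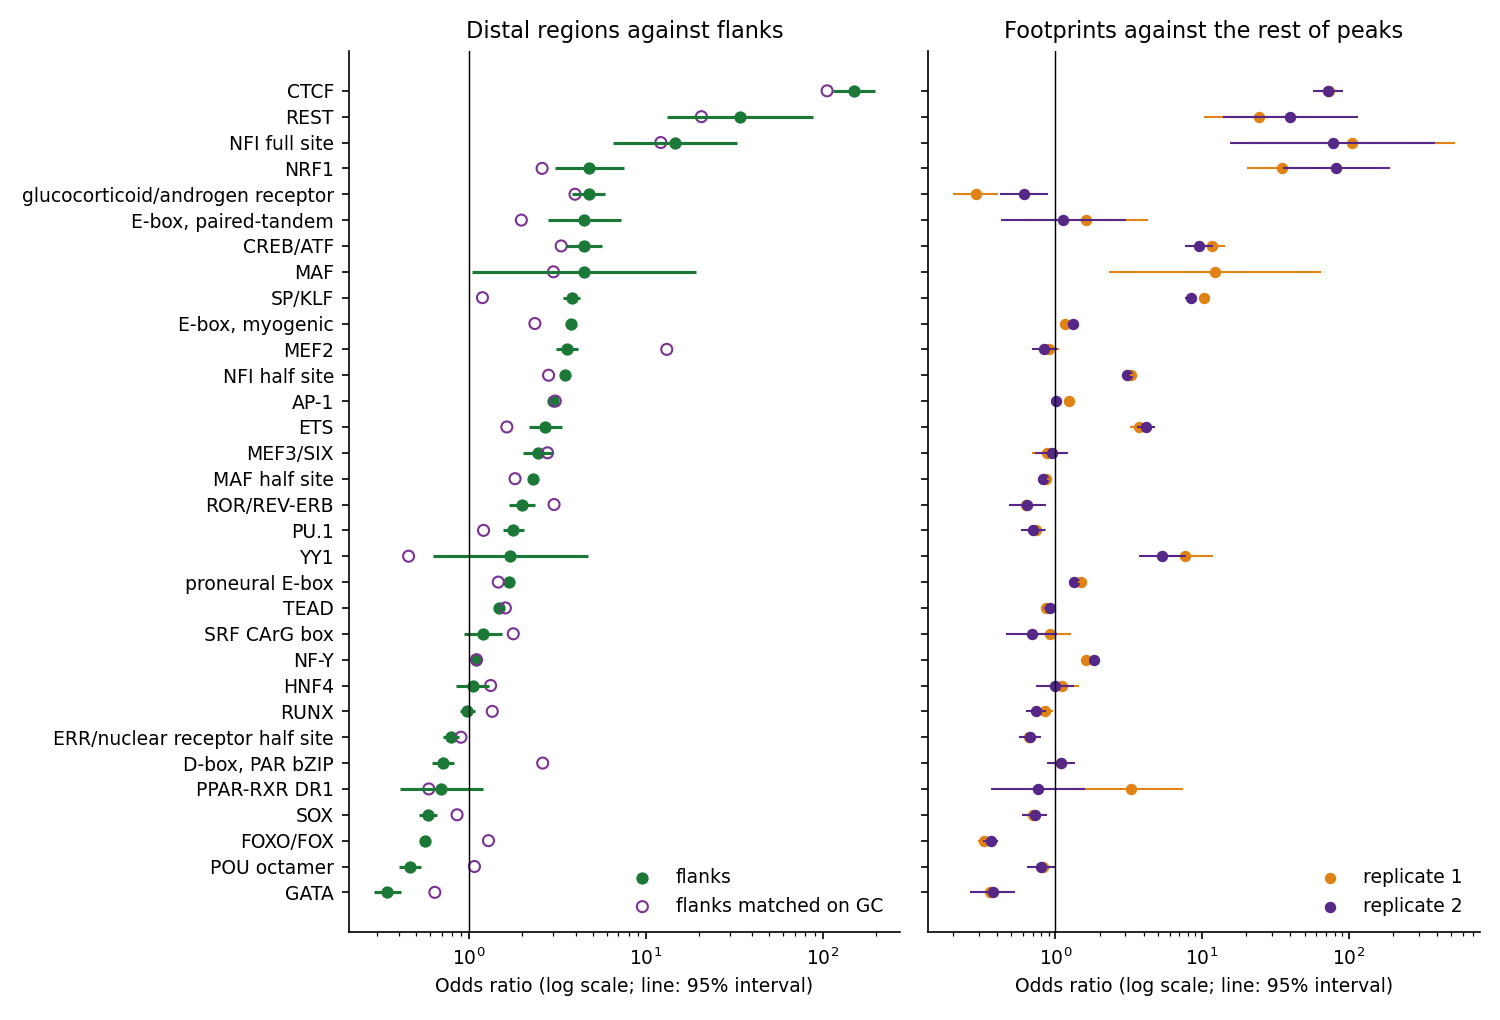
Odds ratios of motifs on a log axis, with lines for 95% intervals. Left, distal regions against flanks (filled) and against flanks matched on GC content (open); right, all footprints of each library against windows of its peaks outside footprints. CTCF stands at 151 on the left, and near 73.0 and 71.8 on the right.

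The signal ratio between the libraries followed base composition. Among distal shared regions the mean log2 ratio of replicate 2 over replicate 1 was -0.21 at a GC content under 45% and 0.37 at 60% and over, a difference of 0.59 (SE 0.013). Among promoter regions the difference was 0.94 (SE 0.063), with 103 regions in the low bin. Promoter and distal regions had unlike mixes of GC content within these bins, so the differences do not show a steeper trend at promoters. The signals of the replicates at single genes, such as Myom1 and Esrra, are therefore set side by side as values only.

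**Figure D4:**
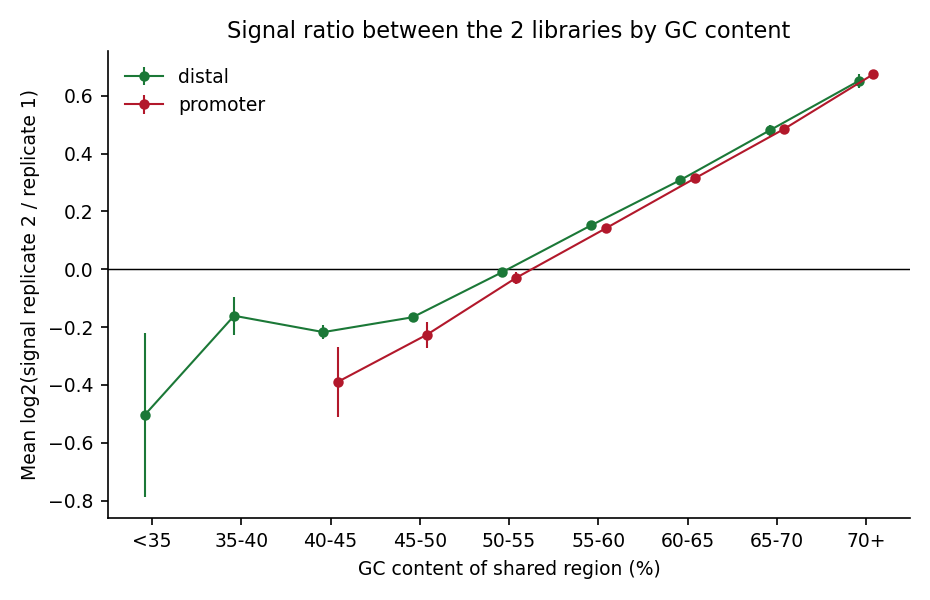
Mean log2 ratio of the authors' signal, replicate 2 over replicate 1, in shared regions binned by GC content (%), for distal and promoter regions apart. Bars are 95% intervals of the mean, and bins with fewer than 20 regions are left out. Distal regions climb from below 0 to 0.65 in the highest bin.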

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

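The values in this part are counts with no test, and none of them was chosen after a test was seen. Footprints were found outside every listed peak. In replicate 1 57445 footprints (12.4%) met no peak of the smaller or the larger file, and in replicate 2 51005 did (12.5%). These footprints lie in data that the comparisons of peaks do not use, and with no control library any number above the limit of a count of 0 was singled out. Nearly all footprints, 462752 of 463993 and 405533 of 407052, lay on bases with a listed false discovery rate under 0.05.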

How the results depend on the processing

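Chosen after the results were seen were the settings without runs of weak peaks, lists, motifs and peak positions in the larger set, 1 gene per neighbourhood, footprints inside peaks, the matched footprint background and every setting of the fast against slow comparison. The mean share of peaks found in both libraries, 72.5%, was 65.4% when 50% of both peaks had to overlap, 85.5% among the strongest 50%, 66.98% in the larger set and 77.9% without runs. With equal numbers of peaks it was 73.8%. For footprints, 53.5% became 39.7% with 50% reciprocal overlap and 68.5% inside peaks of both libraries. The share at promoters, 19.4%, was 23.8% with a 1 kb window, 30.1% among the strongest 50%, 13.9% in the larger set, 20.8% without runs and 19.1 to 19.7% with either replicate left out. The wider window and the changed sets of peaks alter these shares by construction.

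The number of called lists and motifs stayed within 1.5 times under every setting run: 8 to 13 promoter lists against 12, 8 to 10 distal lists against 9, 24 to 29 distal motifs against 26 and 20 to 24 footprint motifs against 23. With either replicate left out these were 10 to 11, 8 to 9 and 27 to 29. Among single lists, 20 promoter values lost a call and 8 gained one, out of 234, and 4 distal values lost and 6 gained one. Counting only motifs called in the main or the other setting, directions turned in 7 cases: with GC-matched flanks the D-box went to 2.61, RUNX to 1.35, FOX to 1.29 and POU to 1.07, and with the matched footprint background MEF2 went to 1.56, RUNX to 1.15 and TEAD to 1.14 (geometric mean over libraries). All 7 turned when GC content was matched. Motifs that crossed 1 without a call on either side were not counted, among them MEF2 in footprints with no extension (1.07) and in footprints inside peaks (1.22). For other changes the cause was not tested. The fast against slow promoter difference, 37.5 points, lost its call at 22.3 and 30.4 points without replicate 1 and without replicate 2 and at 29.5 in the larger set, and the distal difference, 4.43 regions per gene, lost it at 1.92 among the strongest 50%. Of single named genes, 29 of 1050 promoter calls and 475 of 1050 distal counts moved. A distal count moved if it changed by at least the SD between the libraries. Where the libraries had equal counts, any change was enough. Other flanks and peak sets alter these counts by construction. Of the 10 densest genes 3 to 8 stayed under the 5 kb, 50 kb, strongest 50%, larger-set and no-runs settings, 1 in replicate 2 alone and 5 in replicate 1 alone.

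The stronger 50% of footprints could not be run, because footprints carry no score. No paired analysis was possible because there is 1 group. The effect of depth on weak peaks was not tested; 23215 peaks of replicate 2 had a signal under 0.4. A gene or region without a peak is not shown to be closed. The distal list test called few raised lists of 16 genes in simulation. That simulation adjusted over more lists than the 26 tested here, so the power of the test as run is unknown.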

Other observations

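Chosen after the results were seen were the comparison of distal with promoter regions, the neighbour test and the muscle gene test of runs, and the tests of receptor motifs against a matched background; the other tests here were set out first. Distal regions and promoters held different motifs. Compared with 20543 promoter regions, distal ones were richer in CTCF (6.73% against 0.867%, odds ratio 8.24), ROR/REV-ERB (6.83), the receptor palindrome (6.75), AP-1 (3.72), RUNX (3.59), MEF2 (3.12) and the myogenic E-box (21.9% against 10.5%, 2.37). Promoters held more YY1 (0.0212), ETS (0.0698), NRF1 (0.0858), SP/KLF (0.0947), CREB/ATF (0.189) and NF-Y (0.349). The proneural E-box CAGATGG, not a muscle motif, was also richer in distal regions, at 3.43, above MEF2 and the myogenic E-box. The excess was thus not particular to muscle motifs. No matching on GC content was made in this comparison.

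Peaks of a single library differed in place. Exons held 11.7% of peaks found in replicate 2 alone against 5.24% in replicate 1 alone. Outside runs the shares were 11.75% and 4.62%, and in runs 11.6% and 13.2%, so runs do not account for that excess.

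Runs of weak peaks were mostly in replicate 2. Weak peaks in runs had a GC content -0.89 points from that of weak peaks elsewhere in replicate 2. This argued against GC-rich recovery as what set runs apart, but recovery that raised all weak peaks of that library was not tested. Larger-set peaks of signal 0.2 to 0.4 passed the stricter limit 5.50 times as often in replicate 1 and 9.50 times as often in replicate 2 where the nearest such peak passed. Runs are made of such peaks, so this restates the pattern, and a calling limit that differed from place to place cannot be told apart from other sources. Bodies of muscle genes could also attract runs, since 13 of 71 contractile and glucose genes met one in replicate 2, against a 95th percentile of 7 in length-matched lists and 12 when also matched on shared regions, but these are few beside 1180 runs. In replicate 1 the count was 5, against 95th percentiles of 2 and 5. No difference between groups could be tested, as there is 1 group, and a difference between the animals stays open.

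The signal of replicate 2 over replicate 1 climbed with GC content. Runs as the source were argued against, since the difference between GC-rich and GC-poor distal regions was 0.59 on the log2 scale with and without regions that met a run (0.588 without, 0.587 with). The trend was present over both kinds of region, with 0.59 in distal regions and 0.94 in promoters, which restates the pattern and names no source. At equal GC content, distal and promoter ratios were both 0.31 at 60 to 65%, and 0.65 and 0.67 at 70% and over. At 40 to 45% they were -0.22 and -0.39, the latter on 93 promoter regions. The trend is thus not shown to be steeper at promoters. Recovery or sequencing of GC-rich DNA cannot be told apart from a difference between the animals, which was not tested.

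The receptor palindrome was frequent in distal regions and rare in footprints. In replicate 1 GC content was argued against, as the odds ratio in footprints stayed at 0.331 (0.231 to 0.474) with a matched background. In replicate 2 it was 0.794 (0.531 to 1.19), so there GC content cannot be told apart from a true depletion, the counts being few. In footprints of at least 15 bp the ratios were 0.188 (0.111 to 0.319) in replicate 1 and 0.345 (0.206 to 0.577) in replicate 2. A motif too long for most footprints was argued against on these values, but their background was not matched on GC content. No background was matched on promoter or distal place, and the palindrome favoured distal over promoter regions (odds ratio 6.75). A difference in where footprints and background windows lay was not tested and cannot be told apart from a true depletion. Binding too brief to protect the DNA may also remain as a hypothesis, which was not tested.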
